A study of Mus musculus with 12 samples.

How the data were processed

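RNA from 12 samples was measured on Affymetrix expression arrays, 4 each of sorted CD45-negative SP cells, sorted CD45-negative nSP cells and intact jejunum. Per the labels' protocols, jejunum was taken from mice of 8 to 10 weeks, 3 mice were pooled per sort, dead cells were excluded by propidium iodide, and 50 ng of total RNA was amplified in 2 cycles and labelled with biotin. The groups were taken from the sample titles, which call the 4 samples of a group biological replicates.

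The authors deposited, for each sample, a probe-set signal intensity on a linear scale and a detection call (present, marginal or absent), per the file headers. The software and its version are not given in the sources used here. The values show that each array had been scaled on its own to a mean of 500.0 after trimming 2% from each end. The authors also deposited a series value table of linear intensity values for the same 45101 probe sets, on another scale and with exact zeros. Its processing, centring and scaling are not given in the sources used here, and it served only as an alternative. Each of its columns correlated best with the sample file it belongs to.

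The signals were quantile normalised between arrays, an offset of 16 was added and log2 was taken, with Python 3.11.15 and R 4.3.3. The offset understates the change of dim genes. Of the probe sets, 34958 were annotated to 1 gene symbol, 932 to several and 9160, controls left out, to none listed. Genes were named only from those with 1. Probe sets called present on at least 3 of the 12 arrays were kept, and for each gene the one with the highest mean was used, which left 11861 genes. A gene whose probe sets were all absent on every array of a group has only a bound there. For it the text gives "at least N-fold": the bright group's mean against, per array, the higher of the lowest present signal and the gene's own signal. This bound holds for the probe set used, and others of the gene can change less. It compares group means and carries no sampling error, so a smaller change is not excluded. Where the gene's own signal is the higher on each array, it equals the fold change of the means.

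A model with a mean per group was fitted to all 12 arrays with limma 3.58.1 (lmFit, and eBayes with a trend), and 3 comparisons were taken from it, each two-sided with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Genes higher or lower in SP than in both other groups were called from the larger of the one-sided p values. Of 39 gene lists fixed before the data were examined, 37 had at least 5 measured members and were tested with camera (correlation preset at 0.01), with camera at an estimated correlation and with fry. camera compares a list with all other genes, while fry asks whether its genes move on balance one way. Of 749 list entries, 677 were on the array. The remainder are not analysed here.

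Genes named in the text follow a rule also fixed before the data were examined. It takes, per comparison, the 5 largest rises and 5 largest falls among called genes whose arrays do not overlap between groups, and up to 4 members of each described list that was called. It also takes 28 genes chosen in advance, given in the comparison of SP with nSP.

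The replicate numbers in the titles are shared by the groups. For SP and nSP the deviations of arrays of the same number from their group means correlated at 0.164 to 0.213, so the numbers were taken to pair these arrays. With jejunum the values were 0.091 to 0.168 for SP and 0.094 to 0.144 for nSP, and 8 of 8 arrays correlated best with their own number. The numbers may thus pair the arrays of all 3 groups, which the main fit does not use. The column names in the file headers carry a number that sets replicate 1 of all groups apart from replicates 2 to 4. Its meaning is not given in the sources used here, and it was treated as a possible batch.

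Fits were tested on simulated data made with the real means of the 11861 genes and normal noise of the fitted, pooled spread of each gene. Each gene had the same spread in all 3 groups, whereas the real spreads of some genes differed between groups. The recovery below may thus be better than in the real data. In SP against nSP, 45 of 50 genes changed 4-fold and 21 of 50 changed 2-fold were recovered, with 4 false calls among the unchanged genes. In 20 simulated runs of independent unchanged genes, camera called a list in 2 runs. The number of arrays limits the precision, and the median SE of a log2 change was 0.24.

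Alternatives were tried for the normalisation, the source of the values, the offset, the filter, the choice of probe set, the estimate of the spread, the arrays in the fit, the replicate and header number as blocks, the set test and each array left out in turn. One, replicates 2 to 4 only, was added after seeing the data.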

Results

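RNA from the mouse jejunum, the middle part of the small intestine, was measured on Affymetrix expression arrays in 3 groups of 4 arrays. Cells were released from the mucosa with collagenase and dispase and stained with Hoechst, a DNA dye that some cells pump out. CD45, a surface protein of blood-derived cells, was used to remove leukocytes, and propidium iodide to remove dead cells. The side population (SP) is the CD45-negative fraction with low dye content, and the non-side population (nSP) is the CD45-negative remainder. The group called jejunum is intact tissue that was not sorted. The series title presents the SP fraction as putative intestinal stem cells, so the question was which genes set SP apart from nSP and from the intact tissue. Each sort pooled 3 mice, and 4 sorts were made.

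Between 41.3% and 47.0% of probe sets were called present on each array. Arrays of one group resembled each other more than arrays of different groups, with correlations of 0.923 to 0.953 among SP arrays, 0.927 to 0.945 among nSP arrays and 0.956 to 0.963 among jejunum arrays. The first principal component held 48.2% of the variance and the second 26.3%. The Gapdh 3' to 5' signal ratio, a sign of RNA integrity and amplification, was 3.94 ± 1.32 in SP, 4.84 ± 0.75 in nSP and 3.03 ± 0.54 in jejunum (SD, n = 4 each). The median signal of absent probe sets was 27.8 ± 7.32 in SP, 37.0 ± 7.40 in nSP and 25.1 ± 2.20 in jejunum (SD, n = 4 each). All changes below are on the log2(signal + 16) scale, with the standard error (SE) of the fit, and adjusted p values are from limma with Benjamini-Hochberg adjustment over 11861 genes. Values given as at least N-fold compare group means of the probe set used and carry no sampling error. List p values are from camera with a preset correlation, followed by the value with an estimated correlation. Where a list's count adjusted over the list alone is not given, it equalled the count over all genes.

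Genes of enteroendocrine cells, the hormone-secreting cells of the gut epithelium, were higher in SP than in nSP, and genes of fibroblasts and extracellular matrix were lower. Neither list was called with an estimated correlation (adjusted p = 0.051 and 0.118 with an estimated correlation). By fry, which does not compare a list with other genes, both were called (adjusted p = 9.66e-07 and 1.08e-06). Gcg, which encodes proglucagon, was 21.8-fold higher in SP (log2 change 4.45, SE 0.27, adjusted p = 7.57e-08). Its mean was 14.40 ± 0.48 in SP and 9.96 ± 0.57 in nSP (SD, n = 4 each). Scara5, a ferritin receptor gene, was called absent on every SP array and was at least 103-fold lower there than in nSP (adjusted p = 1.63e-07). Lgr5, Ascl2 and Olfm4, markers of crypt base columnar stem cells, were also lower in SP (list adjusted p = 0.324 with an estimated correlation).

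Among the 24 measured enteroendocrine genes, 22 rose in SP against nSP, 0 fell and 2 were not called (list adjusted p = 1.12e-17, and adjusted p = 0.051 with an estimated correlation). Besides Gcg these included Isl1, an islet and enteroendocrine transcription factor (log2 change 3.89, SE 0.27), the cholecystokinin gene Cck (3.75, SE 0.26) and the secretogranin gene Scg3 (3.72, SE 0.24). The largest rises among all genes with no overlap between the groups were Serpina1c, a serine protease inhibitor gene (4.68, SE 0.24), Gcg, the synaptic vesicle fusion gene Snap25 (4.01, SE 0.27), Isl1 and the kinase gene Pak3 (3.86, SE 0.38).

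Of 23 absorptive enterocyte genes, 13 rose and 0 fell, with 18 higher when adjusted over the list alone (list adjusted p = 4.88e-06, and adjusted p = 0.475 with an estimated correlation). The largest were lactase, Lct (3.12, SE 0.97), the meprin gene Mep1b (2.90, SE 0.72), the peptide transporter gene Slc15a1 (2.83, SE 0.59) and the apolipoprotein gene Apoa1 (2.69, SE 0.71). The call of Lct was lost in 7 of 28 alternatives. Its SD was 2.80 in SP and 1.08 in nSP but 0.11 in jejunum, and the pooled SE takes in all 3 groups. The mean of this list was 9.57 on SP replicate 2 and 11.4 to 13.3 on the other SP arrays, and the means of nSP arrays were 9.52 to 10.3. Goblet cell genes, from the mucus-secreting lineage, rose in 6 of 13 cases and fell in 0, with 8 higher when adjusted over the list alone (list adjusted p = 0.0014, and adjusted p = 0.475 with an estimated correlation). Clca1 (2.19, SE 0.36), Capn9 (2.00, SE 0.38) and Agr2 (1.66, SE 0.31) led these. The goblet mean of SP replicate 1, 12.27, lay within the nSP range of 11.68 to 12.60, against 12.99 to 13.91 on the other SP arrays, with replicate 2 highest.

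Of the metabolic lists, oxidative phosphorylation was not called between SP and nSP, with 3 of 27 genes higher and 1 lower (list adjusted p = 0.303), and the others were higher in SP. Cholesterol synthesis genes rose in 8 of 15 cases and fell in 0 (list adjusted p = 0.0001, and adjusted p = 0.231 with an estimated correlation), led by Sqle (1.66, SE 0.19), with Fdps (1.49, SE 0.27) also among them. Xenobiotic metabolism genes rose in 10 of 20 cases and fell in 1, Ephx1 (-1.35, SE 0.32), with 14 higher and 1 lower when adjusted over the list alone (list adjusted p = 0.000469, and adjusted p = 0.52 with an estimated correlation). Of the 10 calls, that of Cyp2b10 was lost in 18 of 28 alternatives. Fatty acid oxidation genes rose in 7 of 17 cases and fell in 0 (list adjusted p = 0.0315, and adjusted p = 0.538 with an estimated correlation), and glycolysis and hypoxia genes rose in 3 of 18 cases and fell in 0 (list adjusted p = 0.017, and adjusted p = 0.324 with an estimated correlation). Bnip3, a mitophagy gene, led the last of these (1.62, SE 0.23). On SP replicate 2 the xenobiotic mean was 9.48, within the nSP range of 9.43 to 10.26, against 10.64 to 12.93 on the other SP arrays, and its fatty acid oxidation mean, 10.50, lay below all nSP arrays (10.55 to 10.92). Its oxidative phosphorylation mean, 13.15, also lay below all nSP arrays (13.33 to 13.54), and those of the other SP arrays above them (13.63 to 13.70). Its glycolysis and hypoxia mean was 11.38, next to the highest nSP array at 11.36, against 11.89 to 11.91 on the other SP arrays.

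Of 23 fibroblast and matrix genes, 0 rose in SP and 21 fell (list adjusted p = 7.59e-21, and adjusted p = 0.118 with an estimated correlation). Dpt, the dermatopontin gene (-6.08, SE 0.21), and the lumican gene Lum (-5.48, SE 0.33) were among them. Ogn, the osteoglycin gene, was at least 75-fold lower, and Pdgfra, a growth factor receptor gene of mesenchymal cells, at least 58.6-fold lower. Outside this list, Rarres2, the chemerin gene, was at least 75.5-fold lower and the growth factor gene Gdf10 at least 65.7-fold lower. These bounds hold for the probe sets used. Among the detected probe sets of Ogn, Pdgfra and Rarres2 the smallest falls were log2 changes of -3.79, -1.99 and -4.55. Of 8 lymphatic endothelial genes, 5 fell and 0 rose, with 7 lower when adjusted over the list alone (list adjusted p = 0.00057, and adjusted p = 0.324 with an estimated correlation). Mmrn1 fell by 5.57 (SE 0.66), and Pdpn was at least 19.9-fold lower.

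Of 19 crypt base columnar stem cell genes, 13 fell in SP and 0 rose, with 14 lower when adjusted over the list alone (list adjusted p = 1.39e-06, and adjusted p = 0.324 with an estimated correlation). The largest falls were those of Ascl2 (-3.81, SE 0.55), Lgr5 (-3.49, SE 0.44), Cdca7 (-2.91, SE 0.44) and Tnfrsf19 (-2.70, SE 0.42). Cell cycle genes fell in 23 of 27 cases and rose in 0, with 24 lower when adjusted over the list alone (list adjusted p = 2.58e-09, and adjusted p = 0.231 with an estimated correlation), led by the replication licensing genes Mcm3 (-2.86, SE 0.23), Mcm5 (-2.81, SE 0.28) and Mcm6 (-2.19, SE 0.28). In the Wnt pathway list, 12 of 23 genes fell and 2 rose (list adjusted p = 0.0122, and adjusted p = 0.231 with an estimated correlation). The Wnt inhibitor gene Sfrp1 fell by 3.76 (SE 0.42), while another inhibitor gene, Wif1, rose (2.46, SE 0.55).

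All 5 measured tuft cell genes fell (list adjusted p = 0.00803, and adjusted p = 0.356 with an estimated correlation), including Dclk1 (-2.05, SE 0.28) and Rgs13 (-1.75, SE 0.37). Paneth cell genes fell in 4 of 6 cases, with 5 lower when adjusted over the list alone (list adjusted p = 0.0181, and adjusted p = 0.475 with an estimated correlation), led by the phospholipase gene Pla2g2a (-3.29, SE 0.58). The call of Ang4, one of the 4, was lost in 15 of 28 alternatives. The Paneth mean of SP replicate 2, 13.87, lay within the nSP range of 13.69 to 14.91, and the other SP arrays lay at 11.54 to 13.18. Blood stem and progenitor genes fell in 4 of 10 cases (list adjusted p = 0.0415, and adjusted p = 0.231 with an estimated correlation), led by Meis1 (-3.60, SE 0.30), and with the replicate number as a block this list was no longer called (adjusted p = 0.0672). Ribosomal protein genes fell in 9 of 21 cases (list adjusted p = 0.00104, and adjusted p = 0.356 with an estimated correlation), with Rps19 lower by a log2 change of -1.01 (SE 0.12). Smooth muscle, blood endothelial, immediate early and leukocyte lists were not called between SP and nSP.

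Genes named in advance gave a mixed picture between SP and nSP. Abcg2, the main Hoechst efflux transporter, rose by a log2 change of 1.03 (SE 0.20, adjusted p = 0.00113), with means of 12.58 ± 0.38 in SP and 11.55 ± 0.32 in nSP (SD, n = 4 each). Abcb1a differed by 0.89 (SE 0.41, adjusted p = 0.112), and Abcb1b was present on 0 arrays and not tested. Ptprc, the gene of CD45, differed by -0.12 (adjusted p = 0.81). Olfm4 (-2.6, SE 0.37), Cd34 (-3.20, SE 0.40), Mki67 (-1.46, SE 0.29) and Lrig1 (-1.14, SE 0.24) fell. Chga, the chromogranin A gene, rose (1.76, SE 0.15), as did the brush border gene Vil1 (0.80, SE 0.17). The differences of Msi1 (-0.69), Sox9 (0.13), Prom1 (0.03), Cd44 (-0.69), Hopx (-0.03), Tert (-0.50), Kit (0.24), Muc2 (0.85), Lyz1 (-0.29), Epcam (0.33) and Acta2 (-1.34) did not pass the test. With the replicate number as a block, Muc2 (adjusted p = 0.0287) and Acta2 (adjusted p = 0.0157) did. That of Bmi1 (-0.49, adjusted p = 0.0872) did not pass either, and it reversed to 0.50 (adjusted p = 0.016) in the authors' series value table, where probe sets were chosen anew. The 2 probe sets of Bmi1, Sox9 and Epcam pointed in opposite directions. Pecam1 was present on 0 arrays and was not tested, and Ly6a and Sis are not analysed here.

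In all, 3915 genes differed between SP and nSP, 1872 higher and 2043 lower in SP, of which 933 and 1096 changed at least 2-fold. The majority turned in the series value table, with 2156 higher and 2116 lower, while with arrays scaled to one trimmed mean it grew, with 1626 higher and 2379 lower. In 28.4% of genes the 4 SP arrays lay all above or all below the nSP arrays, against 2.9% by chance. Of the 37 tested lists, 16 were called, 7 higher and 9 lower, and 0 with an estimated correlation, while other splits of the same 8 arrays gave up to 20 called lists, and up to 14 where each side held 2 arrays of each group. Replicate 1 of each group carried one number in the file headers and replicates 2 to 4 another. The meaning of this number is not given in the sources used here, and it was treated as a possible batch. With it as a block 4037 genes were called, and in replicates 2 to 4 alone 2685 were. Of the latter 97.0% had the same sign in replicate 1, against 77.1% of all genes.

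**Figure D1:**
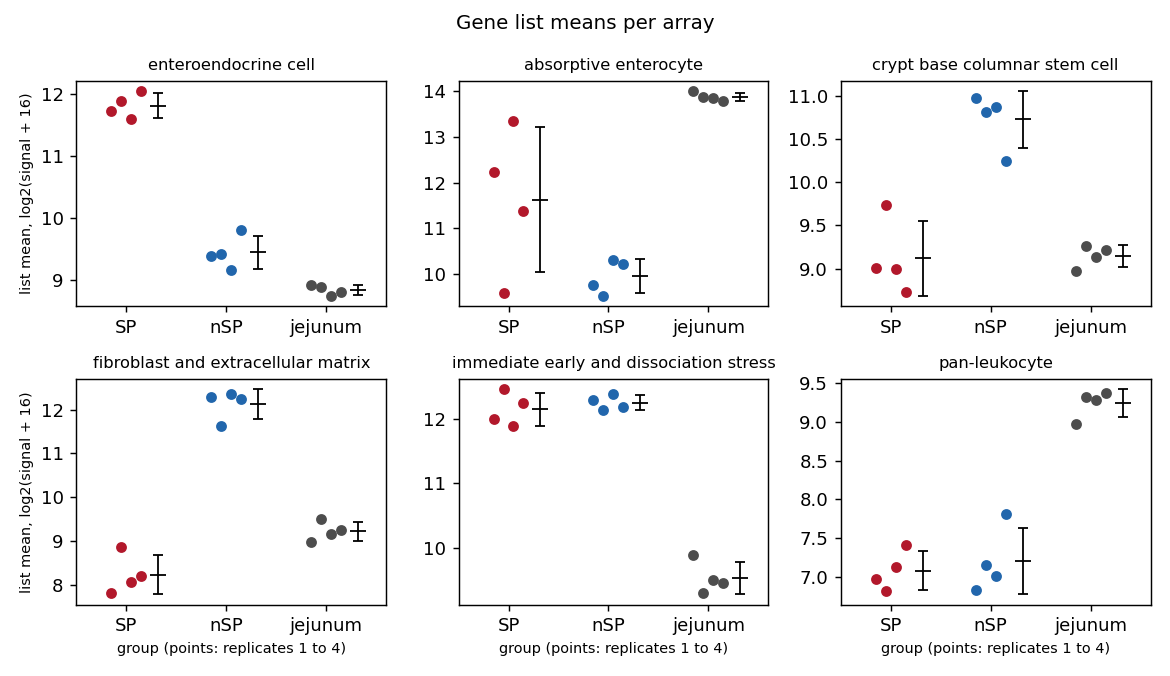
Mean log2(signal + 16) of 6 gene lists on each array, by group, with points for the 4 replicates and bars for the group mean and SD. Enteroendocrine means lie at 11.6 to 12.0 on the SP arrays and 8.74 to 8.92 on the jejunum arrays, and the absorptive mean of SP replicate 2 (9.57) lies apart from the other SP arrays.

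Against the intact tissue, SP carried much higher enteroendocrine and immediate early transcripts and lower smooth muscle, leukocyte and absorptive transcripts. The calls of the leukocyte lists (adjusted p = 0.101 to 0.457 with an estimated correlation) and of the absorptive list (adjusted p = 0.468 with an estimated correlation) were lost in that test, and those of the other 3 lists were kept. By fry, which does not compare a list with other genes, all of these lists were called (adjusted p = 6.07e-08 to 0.0137). Chga was 40.6-fold higher in SP (log2 change 5.34, SE 0.15, adjusted p = 1.51e-11), at 15.10 ± 0.21 against 9.76 ± 0.19 (SD, n = 4 each). Vgf, which encodes a secreted neuroendocrine peptide precursor, was absent on every jejunum array and at least 58.2-fold higher in SP. Actg2, the enteric smooth muscle actin gene, was at least 31.8-fold lower in SP. Ada, the adenosine deaminase gene, fell by 6.03 (SE 0.43).

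Enteroendocrine genes rose in 21 of 24 cases and fell in 2 (list adjusted p = 8.69e-17, and adjusted p = 0.0469 with an estimated correlation). The transcription factor gene Pax4 was at least 23.4-fold higher. The neurotensin gene Nts fell by 2.75 (SE 0.39), and the somatostatin gene Sst was at least 6.04-fold lower. Other large rises were those of the ion channel gene Trpa1, at least 50.2-fold higher, the adhesion gene Amigo2, at least 46.2-fold higher, and the activity-regulated gene Arc, at least 28.4-fold higher. Part of each rise was shared by nSP, most of it for Arc. Trpa1 was at 13.3 in SP, 10.8 in nSP and 7.6 in jejunum, Amigo2 at 11.3, 8.6 and 5.7, and Arc at 9.9, 9.2 and 4.3.

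Immediate early and dissociation stress genes, which respond within minutes to stimuli such as cell isolation, rose in 24 of 26 cases and fell in 0 (list adjusted p = 1.88e-17, and adjusted p = 0.0469 with an estimated correlation). Nr4a1 was at least 31.7-fold higher, Dusp2 at least 22.9-fold and Fosl1 at least 22.1-fold, and Fosb rose by a log2 change of 4.47 (SE 0.50). Heat shock genes rose in 8 of 12 cases and fell in 1 (list adjusted p = 0.000778, and adjusted p = 0.281 with an estimated correlation), led by Hspa1a (3.54, SE 0.36) and Hspa1b (2.51, SE 0.31). The gene that fell was Serpinh1 (-0.79, SE 0.30), a call lost in 21 of 28 alternatives. The Gapdh 3' to 5' ratios of SP arrays (2.21 to 5.43) spanned those of jejunum arrays (2.29 to 3.59).

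Of 12 smooth muscle genes, 12 fell in SP (list adjusted p = 1.6e-09, and adjusted p = 0.0488 with an estimated correlation), including Synpo2 (-4.72, SE 0.34) and Tagln (-4.53, SE 0.48). Pan-leukocyte genes fell in 13 of 14 cases (list adjusted p = 8.08e-07, and adjusted p = 0.101 with an estimated correlation), with Cd52 (-3.83, SE 0.56) and Ptprc (-2.88, SE 0.33) among them. Myeloid and mast cell genes fell in 12 of 15 cases (list adjusted p = 7.73e-05, and adjusted p = 0.137 with an estimated correlation), led by Tyrobp (-3.35, SE 0.36) and Csf1r (-3.30, SE 0.45). T and NK cell genes fell in 9 of 11 cases (list adjusted p = 0.000778, and adjusted p = 0.457 with an estimated correlation), and B and plasma cell genes fell in 8 of 12 and rose in 1, with 9 lower when adjusted over the list alone (list adjusted p = 0.0109, and adjusted p = 0.281 with an estimated correlation). All 6 MHC class II genes fell (list adjusted p = 0.000778, and adjusted p = 0.311 with an estimated correlation), led by H2-Aa (-2.95, SE 0.43). Interferon response genes fell in 11 of 20 cases, with 12 lower when adjusted over the list alone (list adjusted p = 9.81e-05, and adjusted p = 0.255 with an estimated correlation), led by Ifit1 (-4.27, SE 0.32).

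Absorptive enterocyte genes fell in 19 of 23 cases and rose in 0, with 20 lower when adjusted over the list alone (list adjusted p = 8.08e-07, and adjusted p = 0.468 with an estimated correlation). The glucose transporter gene Slc2a2 (-4.36, SE 1.18), the trehalase gene Treh (-3.96, SE 0.89) and Apoc3 (-3.76, SE 0.58) led these. Xenobiotic metabolism genes fell in 13 of 20 cases, with 14 lower when adjusted over the list alone (list adjusted p = 0.000167, and adjusted p = 0.545 with an estimated correlation), led by Cyp1a1 (-3.97, SE 0.69). The xenobiotic mean of SP replicate 3, 12.93, lay within the jejunum range of 12.57 to 13.26, and the other SP arrays lay at 9.48 to 11.47. The epithelial genes Clca4a (-5.84, SE 0.92) and Susd2 (-4.93, SE 0.54) also fell, and Ly6m was at least 31.8-fold lower.

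Cell cycle genes fell in 20 of 27 cases and rose in 0, with 21 lower when adjusted over the list alone (list adjusted p = 2.92e-09, and adjusted p = 0.137 with an estimated correlation). The mitotic kinase gene Aurkb was at least 11-fold lower, and Plk1 (-2.81, SE 0.27) and Nusap1 (-2.74, SE 0.25) fell. Fibroblast and matrix genes fell in 16 of 23 cases and rose in 2, Vim (3.50, SE 0.30) and Thbs1 (3.20, SE 0.34) (list adjusted p = 0.0013, and adjusted p = 0.495 with an estimated correlation). Tuft cell genes fell in 2 of 5 cases, Rgs13 (-2.74, SE 0.37) and Alox5ap (-1.40, SE 0.27), with 3 lower when adjusted over the list alone (list adjusted p = 0.0282, and adjusted p = 0.457 with an estimated correlation).

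Blood endothelial genes rose in 15 of 21 cases and fell in 0, with 16 higher when adjusted over the list alone (list adjusted p = 9.81e-05, and adjusted p = 0.468 with an estimated correlation), including Sox17 (2.70, SE 0.41) and Mmrn2 (1.82). Goblet cell genes rose in 8 of 13 cases and fell in 1, Atoh1 (-1.04, SE 0.38), a call lost in 14 of 28 alternatives (list adjusted p = 0.0191, and adjusted p = 0.61 with an estimated correlation). The goblet mean of SP replicate 1, 12.27, lay within the jejunum range of 12.23 to 12.47, and the other SP arrays lay at 12.99 to 13.91. Candidate reserve stem cell genes rose in 5 of 9 cases and fell in 0 (list adjusted p = 0.0109, and adjusted p = 0.127 with an estimated correlation), led by Sox9 (1.58, SE 0.25), Hopx (1.55, SE 0.18) and Lrig1 (1.34, SE 0.24), whose 3 probe sets did not all point the same way. Ribosomal protein genes rose in 14 of 21 cases (list adjusted p = 1.27e-05, and adjusted p = 0.226 with an estimated correlation), by less than 1 log2 unit each. Crypt base columnar stem cell genes were not called as a list (mean change -0.03, adjusted p = 0.729, and adjusted p = 0.887 with an estimated correlation). Its members went both ways, with 5 of 19 higher and 2 lower, Ascl2 (-1.92, SE 0.55) and Olfm4 (-1.29, SE 0.37).

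In all, 4673 genes differed between SP and jejunum, 2201 higher and 2472 lower in SP, of which 1188 and 1446 changed at least 2-fold. The majority turned to higher genes with arrays scaled to one trimmed mean (2520 higher, 2248 lower) and in the series value table (2753 higher, 2370 lower). In 39.1% of genes the arrays of the groups did not overlap, against 2.9% by chance. Of the 37 lists, 19 were called, 7 higher and 12 lower, and 3 with an estimated correlation, while other splits of these 8 arrays gave up to 20, and up to 14 with 2 arrays of each group on each side. With the header number as a block 4768 genes were called, in replicates 2 to 4 alone 3595 were, and 97.3% of the latter had the same sign in replicate 1, against 79.7% of all genes.

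The nSP fraction differed from the intact tissue in more genes than SP did, with matrix, stem cell and immediate early genes higher and absorptive, muscle and leukocyte genes lower. The calls of all these lists were lost with an estimated correlation (adjusted p = 0.134 to 0.453 with an estimated correlation). By fry, which does not compare a list with other genes, all were called (adjusted p = 7.4e-07 to 0.0111). Scara5 was absent on every jejunum array and at least 111-fold higher in nSP, and Ccn1, a matrix-associated signalling gene, rose by a log2 change of 6.45 (SE 0.34, adjusted p = 2.18e-08). Slc2a2 fell by 7.24 (SE 1.18, adjusted p = 0.000158). Its SD was 0.68 in nSP and 0.24 in jejunum but 3.58 in SP, which enters the pooled SE. Pdzk1, a brush border scaffold gene, was at least 149-fold lower, with an SE of 1.1 for its fitted log2 change. Lgr5 rose (2.74, SE 0.44), at 10.93 ± 0.81 in nSP and 8.19 ± 0.26 in jejunum (SD, n = 4 each).

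Fibroblast and matrix genes rose in 22 of 23 cases and fell in 0 (list adjusted p = 5.75e-12, and adjusted p = 0.146 with an estimated correlation). Dpt rose by a log2 change of 5.15 (SE 0.21), Lum by 5.11 (SE 0.33), the decorin gene Dcn by 3.87 (SE 0.26) and Thbs1 by 3.66 (SE 0.34). Inmt was at least 71.2-fold and Pcolce2, a collagen-processing enhancer gene, at least 56.1-fold higher, and Gdf10 rose (5.65, SE 0.43). Crypt base columnar stem cell genes rose in 17 of 19 cases and fell in 0, with 17 higher and 1 lower when adjusted over the list alone (list adjusted p = 5.05e-06, and adjusted p = 0.298 with an estimated correlation), including Lgr5, Smoc2 (2.49, SE 0.25), Cdca7 (2.32, SE 0.44) and Rnf43 (1.97, SE 0.30). Candidate reserve stem cell genes rose in 5 of 9 cases (list adjusted p = 0.00478, and adjusted p = 0.134 with an estimated correlation), with Lrig1 (2.48, SE 0.24) and Dclk1 (1.49, SE 0.28) among them, although probe sets of both disagreed in direction. Blood stem and progenitor genes rose in 6 of 10 cases, with 7 higher when adjusted over the list alone (list adjusted p = 0.0467, and adjusted p = 0.182 with an estimated correlation). Cd34, shared with the endothelial list, was at least 23.1-fold higher.

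Blood endothelial genes rose in 16 of 21 cases and fell in 0, with 18 higher when adjusted over the list alone (list adjusted p = 0.000182, and adjusted p = 0.453 with an estimated correlation), including Tek (2.41, SE 0.29). Immediate early genes rose in 22 of 26 cases and fell in 1, Klf4 (-0.50, SE 0.17), a call lost in 9 of 28 alternatives, with 23 higher and 1 lower when adjusted over the list alone (list adjusted p = 2.76e-12, and adjusted p = 0.134 with an estimated correlation). Nr4a1 was at least 48.0-fold higher and Fosb rose (4.97, SE 0.50). Heat shock genes rose in 10 of 12 cases (list adjusted p = 4.73e-05, and adjusted p = 0.182 with an estimated correlation), led by Hspa1a (4.57, SE 0.36). Ribosomal protein genes rose in 19 of 21 cases (list adjusted p = 1.08e-07, and adjusted p = 0.146 with an estimated correlation), led by Rps19 (1.86, SE 0.12). The Gapdh 3' to 5' ratio was 3.84 to 5.54 on nSP arrays and 2.29 to 3.59 on jejunum arrays, while the Actb ratios overlapped, 2.94 ± 0.46 against 2.51 ± 0.56 (SD, n = 4 each).

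All 23 absorptive enterocyte genes fell (list adjusted p = 1.55e-11, and adjusted p = 0.327 with an estimated correlation), including Lct (-6.54, SE 0.97), Slc15a1 (-6.50, SE 0.59) and Apoc3 (-5.77, SE 0.58). Xenobiotic metabolism genes fell in 18 of 20 cases and rose in 1 (list adjusted p = 1.53e-07, and adjusted p = 0.365 with an estimated correlation), and fatty acid oxidation genes fell in 10 of 17 and rose in 1 (list adjusted p = 0.00482, and adjusted p = 0.474 with an estimated correlation). Acaa1b fell by 4.34 (SE 0.69). Oxidative phosphorylation genes fell in 8 of 27 cases (list adjusted p = 0.00963, and adjusted p = 0.623 with an estimated correlation), cholesterol synthesis genes in 7 of 15 (list adjusted p = 0.0222, and adjusted p = 0.399 with an estimated correlation) and apoptosis genes in 9 of 19, with 2 higher (list adjusted p = 0.0423, and adjusted p = 0.298 with an estimated correlation). Smooth muscle genes fell in 11 of 12 cases (list adjusted p = 2.4e-07, and adjusted p = 0.134 with an estimated correlation), with Synpo2 (-4.50, SE 0.34). Clca4a was at least 165-fold and Bst1 at least 111-fold lower, and the nuclease gene Dnase1 fell by 7.58 (SE 0.97).

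Leukocyte lists were also lower in nSP than in jejunum. Pan-leukocyte genes fell in 12 of 14 cases (list adjusted p = 2.55e-05, and adjusted p = 0.146 with an estimated correlation), among them Cd52 (-3.61, SE 0.56), Cytip (-3.21, SE 0.37) and Ptprc (-2.76, SE 0.33). Myeloid genes fell in 11 of 15 cases and rose in 1, Lyz2 (1.40, SE 0.50) (list adjusted p = 0.000146, and adjusted p = 0.146 with an estimated correlation), and in the authors' series value table the sign of Lyz2 reversed, to -0.14. T and NK genes fell in 9 of 11 cases, with 10 lower when adjusted over the list alone (list adjusted p = 0.0041, and adjusted p = 0.453 with an estimated correlation). B and plasma cell genes fell in 7 of 12 cases and rose in 1 (list adjusted p = 0.0482, and adjusted p = 0.365 with an estimated correlation). MHC class II genes fell in 5 of 6 cases, with 6 lower when adjusted over the list alone (list adjusted p = 0.00309, and adjusted p = 0.365 with an estimated correlation), and interferon response genes in 12 of 20 (list adjusted p = 0.00309, and adjusted p = 0.365 with an estimated correlation).

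In all, 6019 genes differed between nSP and jejunum, 3142 higher and 2877 lower in nSP, of which 1776 and 1682 changed at least 2-fold. With arrays scaled to one trimmed mean instead of quantile normalised the split was 4116 higher and 2454 lower, a median shift of 0.28 over all genes against 0.06. In 47.2% of genes the arrays of the groups did not overlap, against 2.9% by chance. Of the 37 lists, 21 were called, 8 higher and 13 lower, and 0 with an estimated correlation, while other splits of these 8 arrays gave up to 21, and up to 9 with 2 arrays of each group on each side. With the header number as a block 6128 genes were called, in replicates 2 to 4 alone 4927 were, and 96.5% of the latter had the same sign in replicate 1, against 81.9% of all genes.

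SP was compared with both other groups at once to find genes that set it apart. Enteroendocrine genes made up the largest listed share of those higher in SP: 18 of 24 measured members, where 0.80 would be expected from the overall share (Fisher's exact test, one-sided, adjusted p = 1.58e-20). They included Chga, Gcg, Cck, Isl1 and Pax4. Of the genes lower in SP than in both, 15 were fibroblast and matrix genes out of 23 measured, with 0.62 expected (adjusted p = 3.15e-17, one-sided Fisher's exact test), and 6 were cell cycle genes out of 27 (adjusted p = 0.00166, one-sided Fisher's exact test). Another 3 were lymphatic endothelial genes out of 8, with 0.22 expected (adjusted p = 0.0146, one-sided Fisher's exact test). Fisher's test takes the genes of a list as independent. By camera, for SP against nSP and against jejunum in turn, the fibroblast list had an adjusted p = 0.118 and 0.495 with an estimated correlation, the cell cycle list 0.231 and 0.137, and the enteroendocrine list 0.051 and 0.0469. The lymphatic endothelial list had 0.324 and 0.573.

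In this test 397 genes were higher and 320 lower in SP than in both other groups. Both comparisons use the same SP arrays, so a chance value was needed. Simulated unchanged groups gave at most 0 genes in 20 runs. They held no gene changed in only 1 comparison, so they do not give the chance value for shared SP arrays. Other drawn splits of the real arrays, which mix the groups, gave up to 268 higher and 135 lower genes. Called in both comparisons separately were 660 higher and 616 lower genes, where independent lists would share 347 and 426, and with the SP arrays divided between the comparisons the overlap was 374 to 492 and 342 to 399, against 128 to 328 and 165 to 379 for independent lists. The count of lower genes was 194 without jejunum replicate 2 and 212 without jejunum replicate 3, and in replicates 2 to 4 alone the counts were 250 higher and 163 lower, whereas the series value table gave 606 higher.

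**Figure D2:**
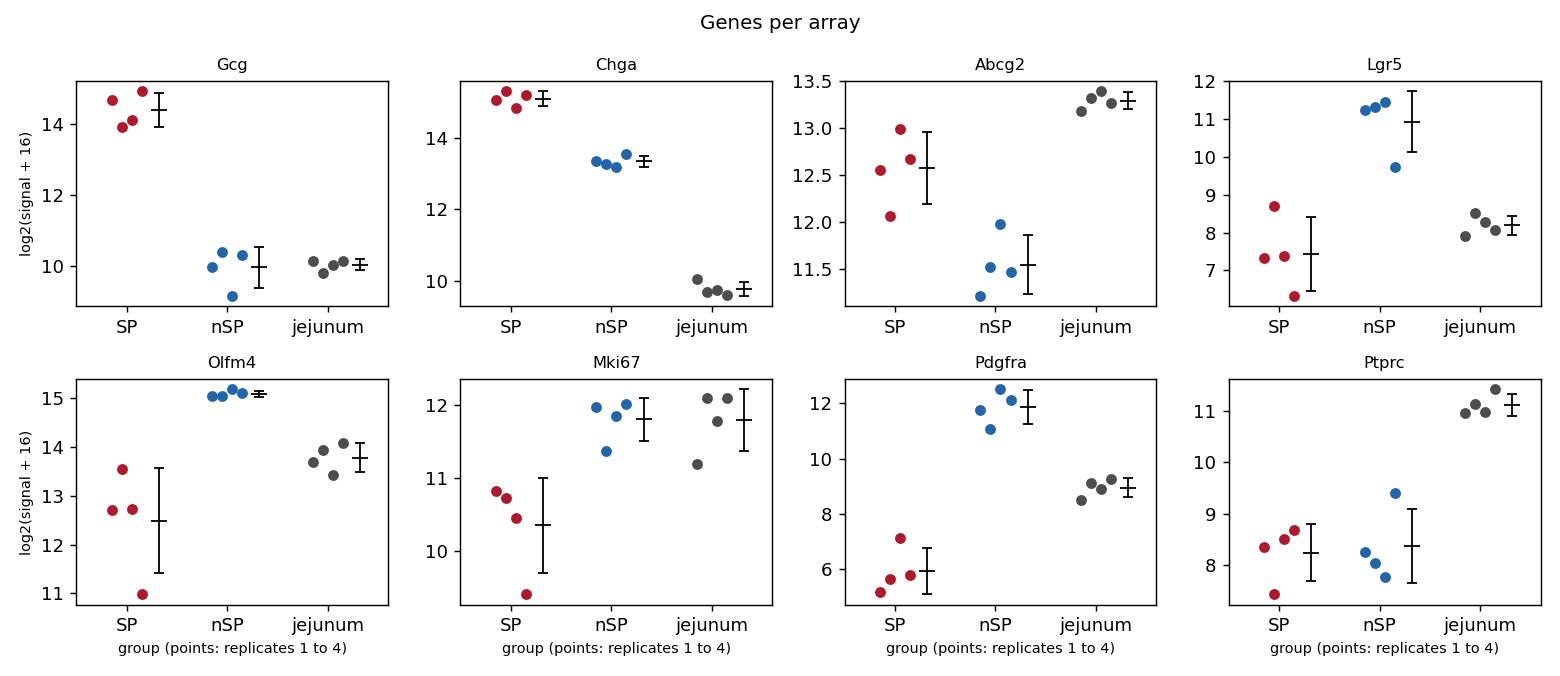
Log2(signal + 16) of 8 genes on each array, by group, with points for the 4 replicates and bars for the group mean and SD. Gcg and Chga are highest in SP, Lgr5, Olfm4 and Pdgfra highest in nSP, and Abcg2 and Ptprc highest in jejunum (Ptprc at 11.12 ± 0.21).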

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

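The tests of array scaling and of a general epithelial gain were chosen after the results they bear on had been seen, and so were the permutations of list means.

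Of 123 sets of 4 arrays examined, covering array measures and list means, 12 held an array far from the other 3, where about 6.2 would be expected, since chance picks out about 1 in 20. In SP, replicate 2 had a median signal of 106.4 (others 77.0 to 81.8), an oxidative phosphorylation mean of 13.15 (13.63 to 13.70) and a glycolysis mean of 11.38 (11.89 to 11.91). SP replicate 3 had a heat shock mean of 11.80 (12.30 to 12.35). In nSP, replicate 4 had a median signal of 128.0 (98.8 to 103.0), a Wnt pathway mean of 8.80 (9.16 to 9.18) and an MHC class II mean of 10.27 (8.82 to 9.0). Present calls on nSP replicate 3 were 47.0% (41.5% to 42.3%), and its xenobiotic metabolism mean was 10.26 (9.43 to 9.56). The fibroblast and matrix mean of nSP replicate 2 was 11.63 (12.24 to 12.35) and its pancreatic acinar mean 9.74 (8.53 to 8.72). The enteric neuron and glia mean of nSP replicate 1 was 6.31 (6.96 to 7.01).

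The gene counts of the real grouping were larger than those of every other split tried. This argues against chance but does not exclude it, since 35 splits can give no share under 0.0286. Only 1 of the 35 splits of the 8 arrays, the real one, gave as many changed genes in SP against nSP (3915, highest other 56), in SP against jejunum (4673, highest other 0) and in nSP against jejunum (6019, highest other 0). The splits of SP and nSP that part all 4 pairs gave at most 0 genes besides the real one, but are too few for a share under 0.05. With the pairs kept, the splits therefore cannot decide the question. For genes higher in SP than in both, 1 of 100 drawn splits, the real one, gave as many (397, highest other 268), and likewise for genes lower in SP than in both (320, highest other 135). These splits were drawn without regard to the replicate numbers, so they do not keep the pairs.

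For the counts of called lists chance cannot be excluded by the share of splits. In SP against nSP 4 of 35 splits gave as many lists as the real 16 (highest other 20), in SP against jejunum 5 of 35 gave as many as 19 (highest other 20), and in nSP against jejunum 3 of 35 gave as many as 21 (highest other 21). Each of the other splits that gave as many had 3 arrays of one group on one side, so it kept part of the group difference. Splits with 2 arrays of each group on each side gave up to 14, 14 and 9 lists, below the real counts. By an exact two-sided permutation test of each list's mean, 11 of the 16 called lists, 17 of the 19 and 21 of the 21 reached the smallest p that 35 splits can give, 0.0286. The called lists that did not reach it were absorptive, goblet, Paneth, fatty acid oxidation and xenobiotic metabolism in SP against nSP, and goblet and xenobiotic metabolism in SP against jejunum. Over all 37 lists, called or not, 17, 22 and 27 reached it. Adjusted over the 37 lists that p became 0.0622, 0.0481 and 0.0392, so no list mean passed 0.05 in SP against nSP by this test.

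Enteroendocrine genes were higher in SP than in both other groups. The choice among the array scalings tried does not account for this. Without normalisation between arrays and in the series value table the mean change of the list was at least 2.22 in both comparisons. Unscaled signals were not tested. A gain of all epithelial cells alike is argued against, since against jejunum the list rose by 2.22 more than the goblet list (SD 0.60 over SP arrays), and by more than that against the absorptive and pan-epithelial lists. Enteroendocrine cells or their precursors may therefore be enriched in the SP gate, which is a hypothesis found and tested on the same arrays. Part of the rise over jejunum was shared by nSP. In nSP against jejunum 11 of the 24 genes rose and 4 fell, with a mean change of 0.61. The list was not called by camera (adjusted p = 0.0668, and adjusted p = 0.5 with an estimated correlation) but was by fry (adjusted p = 0.000514). Chga was at 13.34 ± 0.16 in nSP and 9.76 ± 0.19 in jejunum (SD, n = 4 each). A change in expression within other SP cells was not tested and stays open.

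Fibroblast and matrix genes were higher in nSP than in SP and jejunum. The choice among the array scalings tried does not account for this, with a mean list change of at least 2.83 in nSP against jejunum under both alternatives. Unscaled signals were not tested. Stromal cells in the nSP gate are a candidate source. The test used 22 fibroblast genes outside the fixed list, chosen without reference to their values but kept only if they passed the detection filter. Their median change was 3.10 in nSP against jejunum and -4.45 in SP against nSP. Col3a1, among the most abundant, was at 14.68 ± 0.21 in nSP, 9.29 ± 1.12 in SP and 11.64 ± 0.19 in jejunum (SD, n = 4 each), and 11 of the 22 genes were present on at least 3 jejunum arrays. The others needed present calls on sorted arrays to pass the filter, which favours a rise in nSP among them. The CD45 gate would not remove stromal cells, and expression of these genes by other nSP cells was not tested.

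Crypt base columnar stem cell genes were lower in SP than in nSP. The choice among the array scalings tried does not account for this, since the mean change of the list was at most -1.61 under both alternatives. Unscaled signals were not tested. Whether stromal cells in nSP carry the same genes cannot be told apart from a difference in stem cells. The median change of 11 stem cell genes outside the fixed list was -1.63, with quartiles of -2.72 and -0.68. The median passed the bound against stroma that was set in advance, but the upper quartile did not, a stricter reading adopted after the value was seen because whether stroma expresses these genes was not measured here.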

How the results depend on the processing

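One setting, replicates 2 to 4 only, was chosen after seeing the data. The numbers of changed genes and of called lists stayed within 1.5 times their values under every alternative set before the data were examined except an estimated correlation in camera, with which 0, 3 and 0 lists were called in SP against nSP, SP against jejunum and nSP against jejunum. With fry 21, 24 and 25 were called in the same order, and 3 calls by camera were lost. These were fatty acid oxidation and xenobiotic metabolism in SP against nSP (adjusted p = 0.106 and 0.0711 by fry) and goblet in SP against jejunum (adjusted p = 0.0662 by fry). Among named genes and comparisons, 7759 values kept their side of the threshold, 217 were no longer called, 52 became called and 2 reversed. For lists these were 3148, 104 and 69, with 0 reversed. A reversal was counted only where the main fit or the alternative made a call. The kept values can thus include uncalled ones that changed direction. The reversals were Bmi1 in SP against nSP (0.498) and Lyz2 in nSP against jejunum (-0.143), both in the series value table, and the cause was not tested. There the probe set of each gene was chosen anew, so it may differ from that of the main fit. The 2 probe sets of Bmi1 gave -0.49 and 0.40 in the sample files.

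Genes higher in SP than in both numbered 606 in the series value table (cause not tested) and 250 in replicates 2 to 4 alone, and genes lower than in both 163 there, with fewer arrays in the fit. Leaving out 1 array gave 299 to 410 higher and 194 to 361 lower genes, 3280 to 4156, 3968 to 4722 and 5324 to 6291 changed genes in the same order of comparisons, and 15 to 20, 18 to 21 and 18 to 22 called lists. The lowest counts of lower genes were 194 without jejunum replicate 2 and 212 without jejunum replicate 3. With only the arrays of the 2 compared groups in the fit, 3184, 4707 and 6209 genes were called in SP against nSP, SP against jejunum and nSP against jejunum.

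With the replicate number as a block, 4220, 5008 and 6327 genes were called, 477 higher and 374 lower in SP than in both, all within 1.5 times. In SP against nSP, where the numbers pair the arrays, the block ended the call of the blood stem list (adjusted p = 0.0672), added calls of Acta2, Muc2 and the heat shock list (adjusted p = 0.0475) and changed no other call of a list or named gene. In SP against jejunum and nSP against jejunum same-number correlations were 0.091 to 0.168 and 0.094 to 0.144, and different-number ones at most 0.072 and 0.045. With 8 of 8 arrays correlating best with their own number, these arrays may be paired too. The block changed no call of a list or named gene in SP against jejunum. In nSP against jejunum it added those of the lymphatic endothelial list (adjusted p = 0.046), Epcam (adjusted p = 0.0168) and Tert (adjusted p = 0.0462). With arrays scaled to one trimmed mean, the median change over all genes in SP against nSP moved from -0.01 to -0.12. Probe sets near background limit dim genes, since log2(signal + 16) understates their change.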

Other observations

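The hypothesis below was formed from the fixed cell cycle list. Its test used other genes, chosen without reference to their values but kept only if they passed the detection filter.

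In nSP against jejunum the cell cycle list was not called (adjusted p = 0.251), with 8 of its 27 genes higher and 12 lower, and 8 higher and 14 lower when adjusted over the list alone. The replication licensing genes and the mitotic genes went opposite ways. Of 19 other DNA replication genes, 13 rose and 0 fell (median change 0.84). Of 21 other mitosis genes, 0 rose and 18 fell (median change -1.13). The medians differed by 1.97. In SP against jejunum 10 of the replication genes fell and 1 rose, and 19 of the mitosis genes fell.

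A candidate explanation of the difference of 1.97 is that nSP held relatively more cells in DNA replication and fewer in mitosis than the intact wall, for example if cells with doubled DNA content, which are brighter in Hoechst, were gated out. The gates are not analysed here, so the reason was not tested.

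Lists not called in SP against nSP included enteric neuron and glia genes (5 of 12 higher and 2 lower, 6 higher and 2 lower when adjusted over the list alone, adjusted p = 0.0756), among which Snap25 and Nefl are also expressed by endocrine cells. Of this list, Nefl, Nefm, Ret and Snap25 were higher in SP than in both other groups, where 0.40 would be expected (adjusted p = 0.00914, one-sided Fisher's exact test, which takes genes as independent). By camera the list was called neither in SP against nSP (adjusted p = 0.475 with an estimated correlation) nor in SP against jejunum (adjusted p = 0.39, and adjusted p = 0.691 with an estimated correlation). By fry it was called higher in both (adjusted p = 0.00649 and 0.0117), although against jejunum 4 of its genes rose and 3 fell.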
